A study of Zea mays with 24 samples.

How the data were processed

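RNA-seq libraries were made from 4 segments of leaf 2 of maize W22 seedlings, wild type and dct2-1, 3 replicates per genotype and segment (24 libraries). Per the labels, each replicate pooled 15 plants grown for 9 days with 16 h of light per day at 500 umol per square metre and second, 28 degrees C and 40% humidity. Groups were taken from the labels. The labels number the replicates, but nothing in the tables used here carries a replicate number.

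Reads were aligned with GSNAP and compared with Cuffdiff, per the submitters' processing notes; versions, genome build and annotation are not given in the sources used here. The deposited tables follow Cuffdiff's layout, per the file headers. Each holds an FPKM value (fragments per kilobase of transcript, scaled to library size) for groups q1 and q2, pooled over the replicates of a group by the authors, a test statistic (a score with no fixed range), a p-value and a q-value (here adjusted p), all computed by the authors, and a status for each gene. The segment of each table comes from the sample descriptions. The deposited log2 fold change column was not used because some of its cells hold a spreadsheet error in place of a value; fold changes were recomputed as log2 of q2 FPKM over q1 FPKM, and no fold is given where a group is listed at 0.

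Every table lists 39634 genes. Status OK, meaning tested by the authors, was held by 20174, 18810, 17969 and 16272 genes at segments -4, -1, +4 and +10. At +4, 2 genes had too much data to be tested (pep1 and pdk1) and for 1 gene, cncr1, the test failed. The flag for significance in the deposited tables equals an adjusted p under 0.05 for every gene, and that was the threshold for a call. The smallest deposited p-value is 5e-05, so adjusted p-values have a floor of 0.000492, 0.000777, 0.000288 and 0.000259 in the 4 tables and do not rank genes at the floor. Replicate values were not analysed here, so no SD could be computed, and p-values rest on the authors' own estimate of the spread between 3 pooled samples per group. The standard error of a log2 fold change was taken as its size over the deposited statistic. A normal p from that statistic was larger than the deposited p (median ratio of deposited to normal p from 0.342 to 0.507), so a normal test on this error gives a larger p for a gene than the deposited one. Read depth per library is unknown, and no counting interval can be given. How strand and reads shared by near-identical genes were handled is not given in the sources used here, so values for families such as histones, small heat shock proteins, rbcS and chlorophyll-binding proteins are uncertain.

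Differences between segments were tested with a two-sided normal test on the difference of 2 log2 fold changes, with Benjamini-Hochberg adjustment over genes with a statistic in both tables. That test is a normal approximation resting on 3 pooled samples per group, and no exact test was possible without values per library, so its p-values are not printed. The test takes the errors of the 2 tables as independent, which was not checked. Overlaps were compared with n1 x n2 / N among genes tested in both tables. Gene lists were tested with Fisher's exact test (two-sided) against all genes tested in the segment, per direction, for lists with at least 3 tested members, adjusted over 52 tests for lists fixed before the data were examined and over 214 tests for lists added later. Genes of a list are not independent replicates, so these p-values do not measure the spread between samples. List medians were set against 10000 random lists matched on mean expression in 20 bins and, as a closer match for abundant genes added after the results were seen, against 10000 lists drawn from the 50 non-members closest in mean FPKM to each member. Of 22 lists fixed beforehand, 10 matched no gene and 9 matched at least 3, because the name table used here holds symbols and no descriptions. A further 29 lists were therefore defined: 27 by symbol, after a first look at the tables that showed values of a few genes but before values of the lists were seen, and 2 by chromosome (plastid and mitochondrial genome), after the first results were seen. After the matches were listed, 10 gene and list pairs whose symbol names another gene were removed, 2 of them from the cell cycle list fixed beforehand. Names came from a table of RefSeq genes for assembly Zm-B73-REFERENCE-NAM-5.0, which matched 18774 of the 39634 identifiers and gave a usable symbol to 2649; its coordinates were not used.

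Genes named in the text follow a rule set before the data were examined, which asked for a gene description; as none was given, a usable symbol took its place after the tables were seen. The rule takes pDCT2, every C4 core gene; in each segment the 8 largest rises and 8 largest falls among called genes with a symbol and at least 5 FPKM in the higher group; up to 4 called members per list and segment with the largest change; and up to 10 genes per direction called in all 4 segments. bx9 was named outside the rule, after its values were seen. cncr1 (failed test at +4) and BX14 were picked the same way but also meet the rule, through the lignin and benzoxazinoid lists at -4.

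The difference test was tested on simulated data with 200 planted differences, 100 of each size, on noise drawn from the implied standard errors. The list test was tried separately, on gene lists drawn at random. Against +4, the share of 4-fold differences recovered was 51%, 38% and 40% for segments -4 (16374 genes), -1 (16995) and +10 (15993), and of 2-fold differences 2%, 4% and 10%. False calls made up 3.64%, 8.70% and 5.66% of all calls there (2 of 55, 4 of 46 and 3 of 53), above the nominal 5% for -1 and +10. The noise followed the same errors that the test assumes, so the simulation cannot check those errors. Alternatives tried were a stricter threshold, a 2-fold minimum (counts with it include called genes with a group at 0, of which there were 7, 14, 28 and 26 from -4 to +10), a filter of 1 FPKM, other sets of tests for the adjustment, centring on the median gene and a pseudocount of 1 FPKM. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.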

Results

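The data came from the second leaf of maize seedlings of the inbred W22, sampled in 4 segments named by their distance from a ligule, the hinge between the blade and sheath of a leaf. Segment -4 lies at the base of the growing blade and does not yet photosynthesise, segment -1 lies where the tissue turns from importing to exporting sugar, segment +4 is lit mid-leaf tissue and segment +10 is the tip. Wild-type plants and plants homozygous for dct2-1, a mutant allele of the plastid dicarboxylate transporter gene pDCT2, were compared. In C4 leaves such a transporter carries malate into bundle sheath chloroplasts. The labels list 24 libraries in 8 groups, 3 per genotype and segment, each made from 15 pooled plants of 9 days.

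The authors' deposited tables, 1 per segment, give for each of 39634 genes a single FPKM value for each of 2 groups named q1 and q2, with no value for a single library. The tables do not say which of q1 and q2 is the wild type, so every direction is given as q2 relative to q1, and comparisons across tables take q1 to be the same genotype in each. Levels, test statistics and adjusted p-values below are Cuffdiff's, from the authors' deposited table of the segment. Errors are the standard error of the log2 fold change implied by the deposited statistic, and values in parentheses after a gene are log2 changes with that error. Read depth is unknown, and the sums of FPKM over all genes were 775209 in q1 and 752339 in q2 at segment -4, 800764 and 747022 at -1, 861222 and 629078 at +4, and 857261 and 672724 at +10. The sums at +4 lack pep1 in q1 and pdk1 in q2, which have no usable level there because these genes had too much data to be tested. Part of the gap between the sums at +4 can come from that.

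The first question was whether the pDCT2 transcript itself differed between the 2 groups. It was lower in q2 in all 4 of the authors' deposited tables. The gene (GRMZM2G086258; chromosome 1, 181868559 to 181880941 in the deposited coordinates, build not given in the sources used here) went from 37.8 to 7.84 FPKM at segment -4, from 657 to 12.5 FPKM at -1, from 633 to 8.91 FPKM at +4 and from 310.4 to 9.50 FPKM at +10. The log2 changes of pDCT2 were -2.27 ± 0.27, -5.72 ± 0.35, -6.15 ± 0.34 and -5.03 ± 0.29 in that order, with q1 higher 4.83-fold, 52.7-fold, 71.1-fold and 32.7-fold. Each adjusted p in the authors' deposited tables was the smallest its table can give, from 2.59e-04 at +10 to 7.77e-04 at -1.

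At segment -4, genes of photosynthesis were higher in q2 and genes of cell division were lower. Among the C4 core genes, 9 of 16 tested members rose and 2 fell, with 13 called when adjusted over the list alone. The list held more higher calls than other genes (Fisher's exact test, adjusted p = 0.00224). Genes of a list are not independent replicates, so list p-values here and below describe calls across genes, not samples. The added list of C4 genes chosen by symbol had 7 rises and 3 falls of 15 (Fisher's exact test, adjusted p = 0.0294). In the authors' deposited table, pdk1, pyruvate orthophosphate dikinase, rose from 130.4 to 600.3 FPKM (log2 change 2.20 ± 0.42), pdrp1, the regulatory protein of that enzyme, by 1.82 ± 0.28, pep1, phosphoenolpyruvate carboxylase, by 1.67 ± 0.29 and me3, NADP-malic enzyme, by 1.32 ± 0.27. pDCT1, a related transporter gene, rose by 0.52 ± 0.26, while pDCT2 and GRMZM2G146677 were the members that fell.

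Mesophyll and bundle sheath markers moved the same way at segment -4. Most mesophyll markers are also C4 core genes. The bundle sheath markers include C4 core genes and the 4 fixed Calvin-Benson genes, so these tests in part recount shared genes. Of 8 mesophyll markers 6 rose and 0 fell (adjusted p = 0.00224, Fisher's exact test; 7 called when adjusted over the list alone), and of 8 bundle sheath markers 5 rose and 1, pDCT2, fell (adjusted p = 0.0195; 6 over the list alone). Light-harvesting and thylakoid genes rose in 14 of 20 cases with 1 fall (Fisher's exact test, adjusted p = 2.24e-06). Among them cab-m1, a chlorophyll-binding protein gene, rose by 1.20 ± 0.29 in the authors' deposited table. Genes of Rubisco, its assembly and the Calvin-Benson cycle rose in 7 of 11 cases and fell in 1 (Fisher's exact test, adjusted p = 0.00378), among them the Rubisco activase genes rca3, by 3.16 ± 0.49, and rca1, by 1.89 ± 0.27, and the small subunit gene rbcS, by 1.13 ± 0.29. The 4-gene Calvin-Benson list fixed before the data were examined had 3 rises and 0 falls, which did not pass the enrichment test (Fisher's exact test, adjusted p = 0.0641; 3 over the list alone).

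Of 42 tested genes of DNA replication, cell cycle and histones, 29 fell and 1 rose at segment -4 (Fisher's exact test, adjusted p = 9.52e-15). The ribonucleotide reductase genes RNRS3 (-0.99 ± 0.25) and RNRS1 (-0.98 ± 0.25), which supply deoxynucleotides, and the spindle checkpoint gene mad2 (-1.02 ± 0.35) fell in the authors' deposited table. Ribosomal protein genes fell in 16 of 37 cases and rose in 0 (Fisher's exact test, adjusted p = 7.35e-05), with 7 falls at an adjusted p under 0.01. In the shorter cell cycle list fixed beforehand, 3 of 4 tested members fell (Fisher's exact test, adjusted p = 0.043; 3 over the list alone), namely krp6, MCM6 and MCM7, with 1 fall at an adjusted p under 0.01, and of 4 meristem and ligule markers 0 were tested. Expansins and cellulose synthases, which act on the cell wall, rose in 10 of 20 cases and fell in 1 (Fisher's exact test, adjusted p = 0.00323). Aquaporins rose in 10 of 13 cases and fell in 0 (Fisher's exact test, adjusted p = 2.8e-05), led by pip2f, by 3.84 ± 0.50, and tip2a, by 3.28 ± 0.27.

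The authors' deposited table called 5629 of 20174 tested genes at segment -4 at an adjusted p under 0.05, of which 3062 were higher and 2567 lower in q2. Among called genes with a symbol and at least 5 FPKM in the higher group, the largest rise was that of asn3, an asparagine synthetase gene, from 2.51 to 73.7 FPKM (log2 change 4.87 ± 0.34), followed by the dehydrin gene dhn1, at 4.55 ± 0.58, and AAMT3, at 4.26 ± 0.90 (2.60 for AAMT3 with a pseudocount of 1 FPKM). The largest falls were those of the lipoxygenase gene lox1, from 598 to 42.9 FPKM (-3.80 ± 0.34), the cystatin gene cpi2 (-3.27 ± 0.29), and NAR, a nitrate reductase gene (-3.04 ± 0.36). Genes of the jasmonate list fell in 9 of 19 cases and rose in 1 (Fisher's exact test, adjusted p = 0.00301), and all 8 benzoxazinoid genes fell (adjusted p = 2.43e-06). The jasmonate list was filled by symbol. It holds lipoxygenase genes such as lox1, lox3, lox11 and lox12, whose part in jasmonate synthesis was not checked. With a change of at least 2-fold required 1406 genes were called, 1051 higher and 355 lower, counting 7 called genes with a group listed at 0.

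At segment -1, of 16 tested C4 core genes 1 rose and 4 fell, while 17.7% of all tested genes were called. The C4 core had 5 calls when adjusted over the list alone, with no enrichment in either direction (Fisher's exact test, adjusted p = 0.12 for falls). Apart from pDCT2, the falls were pDCT1 (-0.62 ± 0.34), pOMT1, an oxaloacetate and malate transporter gene of the chloroplast envelope (-0.54 ± 0.33), and GRMZM2G146677 (-0.68 ± 0.36), in the authors' deposited table. The rise was that of alt GRMZM2G088064, alanine aminotransferase, by 1.10 ± 0.51. The log2 changes of pdk1 and me3, 0.01 ± 0.66 and 0.07 ± 0.34, did not pass the test. Mesophyll and bundle sheath markers each had 1 fall and 0 rises among 8 (1 each when adjusted over the list alone), and the 4 Calvin-Benson genes had 0 calls.

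Heat shock proteins and chaperones rose in 12 of 15 cases at segment -1 and fell in 0 (Fisher's exact test, adjusted p = 9.23e-09; 13 over the list alone), and in 9 of 15 with 0 falls at -4 (adjusted p = 0.00153; 10 over the list alone). In the authors' deposited tables hsp18 rose by 2.00 ± 0.36 at -1 and by 2.36 ± 0.28 at -4, and hsp82 by 1.82 ± 0.36 and 2.17 ± 0.31. Heat shock factor genes rose in 6 of 9 cases at -4 (Fisher's exact test, adjusted p = 0.0064), led by Hsf26, by 3.38 ± 1.17, but passed in no other segment, with 2 rises and 0 falls of 8 at -1 and 3 rises and 1 fall of 8 at both +4 and +10 (adjusted p for rises = 0.477, 0.511 and 0.704). The fixed defence and stress list had 2 rises and 0 falls of 10 at -4 and 2 rises and 3 falls of 12 at -1 (2 and 5 over the list alone), without enrichment (Fisher's exact test, adjusted p = 0.973 for rises at -4 and 0.201 for falls at -1). Of 3 phenylpropanoid genes 2 rose at -1 (Fisher's exact test, adjusted p = 0.108; 3 over the list alone).

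Genes of the jasmonate and benzoxazinoid lists fell at segment -1. Of 21 tested genes of the jasmonate list, which includes lipoxygenases taken by symbol, 15 fell and 0 rose (adjusted p = 1.79e-10, Fisher's exact test). The authors' deposited table lists lox5 at 182 to 6.77 FPKM (fell by 4.75 ± 0.40), lox1 at 987 to 74.4 FPKM (-3.73 ± 0.38) and the allene oxide synthase gene aos2 at 149 to 37.0 FPKM (-2.01 ± 0.36), q1 to q2. All 8 benzoxazinoid genes, which make the main defence compounds of young maize, fell (Fisher's exact test, adjusted p = 1.46e-07), among them bx2 (-4.31 ± 0.39), and bx1 (-3.90 ± 0.38). Genes of nitrogen uptake and assimilation fell in 7 of 15 cases and rose in 2 (Fisher's exact test, adjusted p = 0.00124), while asn3, an asparagine synthetase gene, went from 6.28 to 370.3 FPKM (5.88 ± 0.38) and the glutamine synthetase gene gln2 rose by 2.58 ± 0.74. Lignin genes rose in 6 of 13 cases and fell in 0 (Fisher's exact test, adjusted p = 0.0064), among them the laccase genes lac5, by 1.06 ± 0.38, and LAC1 (GRMZM5G842071), by 1.35 ± 0.34. The lignin list had the opposite direction at +4, with 5 falls and 1 rise of 6 (Fisher's exact test, adjusted p = 0.0245), and had 5 falls and 2 rises of 8 at +10 (adjusted p = 0.0887). At -1, TIFY genes fell in 6 of 21 cases and rose in 2 (Fisher's exact test, adjusted p = 0.0402), and anthocyanin and flavonoid genes fell in 4 of 10 and rose in 0 (adjusted p = 0.044). The medians of these lists at -1, -0.14 for TIFY and -0.11 for anthocyanin genes, lay within the central 95% of random lists matched on expression (percentiles 17.2 and 24.7). At -4, TIFY genes had 4 rises and 1 fall of 14, which did not pass (Fisher's exact test, adjusted p = 0.557 for rises).

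The table for segment -1 called 3330 of 18810 tested genes, 1784 higher and 1546 lower in q2. After asn3, the largest rises among named genes in the authors' deposited table were those of EREB94, by 3.79 ± 0.66, and a hydroxyproline-rich glycoprotein gene, HRGP (GRMZM2G168651), by 3.37 ± 0.54. The aquaporin gene tip4a (-4.34 ± 0.71) and the haemoglobin gene Hb2 (-4.10 ± 0.90, or -2.62 with a pseudocount of 1 FPKM) fell. With at least 2-fold change 1589 genes were called, 863 higher and 726 lower, and at an adjusted p under 0.01 there were 2035. Whether -1 or -4 had fewer calls turned with that choice, since -4 had 5629 calls without a minimum and 1406 with the 2-fold minimum, and the median implied standard error was larger at -1 (0.414) than at -4 (0.297).

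At segment +4, light-harvesting genes were lower in q2 and heat shock genes were higher. Of 21 tested light-harvesting and thylakoid genes, 17 fell and 1 rose (adjusted p = 1.42e-06, Fisher's exact test). Whether this fall went beyond that of equally abundant genes was not settled. The list median of -0.94 lay below the central 95% of random lists matched on expression, -0.60 to 0.16 (percentile 0.01). It lay within the central 95% of random lists drawn from the 50 non-members closest in FPKM to each member, -1.00 to -0.27 (percentile 5.86). The list was filled by symbol, so these non-members can include other photosynthesis genes. The closer match therefore cannot tell a fall of photosynthesis genes from a fall of abundant genes. At +4, 62 of the 80 other genes of at least 1000 FPKM were lower. In the authors' deposited table lhcb3 went from 6364 to 452 FPKM (fell by 3.82 ± 0.38), cab-m1 from 7679 to 553 FPKM (-3.79 ± 0.38) and psad1, a photosystem I subunit gene, from 1222 to 235 FPKM (-2.38 ± 0.31). Among 14 tested C4 core genes 6 fell and 3 rose (9 when adjusted over the list alone), with no enrichment (Fisher's exact test, adjusted p = 0.244 for falls). The C4 core median of -0.32 lay at percentile 78.7 of random lists drawn from the 50 non-members closest in FPKM. Of C4 core genes of at least 1000 FPKM, 3 of 7 were lower, against 71 of 85 other genes of that abundance. Besides pDCT2, the members that fell included pDCT1 (-1.36 ± 0.29), pOMT1 (-1.13 ± 0.31), GRMZM2G174107 (-1.00 ± 0.34) and the NADP-malate dehydrogenase gene mdh6 (-0.71 ± 0.35), while me3 stood at 0.19 ± 0.42 and did not pass the test. The authors' deposited table gave no test for pep1 and pdk1 at +4: it lists pep1 at 0 in q1 and at 9116 FPKM in q2, and pdk1 at 27347 FPKM in q1 and at 0 in q2, under a status for loci with too much data, so neither 0 was read as a level.

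Rubisco activase rca3 went the other way at segment +4, rising from 83.2 to 349 FPKM (2.07 ± 0.29), while rbcS fell by 0.97 ± 0.35. Mesophyll markers fell in 4 of 6 tested cases and bundle sheath markers in 4 of 8, with 0 and 1 rises, and neither passed the enrichment test (Fisher's exact test, adjusted p = 0.108 and 0.219; 4 and 5 over the list alone). The fixed Calvin-Benson list had 3 falls of 4 (Fisher's exact test, adjusted p = 0.12; 3 over the list alone). All genes above 1000 FPKM as the mean of both groups had a median log2 change of -0.95 (92 genes, 74 lower), against -0.16 for the 898 genes between 100 and 1000 FPKM.

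Heat shock proteins and chaperones rose in 12 of 15 tested cases and fell in 0 at segment +4 (Fisher's exact test, adjusted p = 1.9e-05; 12 over the list alone). hsp18 went from 31.1 to 708 FPKM (rose by 4.51 ± 0.34) and hsp82 from 6.36 to 133 FPKM (4.38 ± 0.35) in the authors' deposited table. Falls were called for 14 of 17 genes of the jasmonate list (Fisher's exact test, adjusted p = 1.01e-05) and 10 of 15 TIFY genes (adjusted p = 0.00378). The TIFY family includes jasmonate-response repressors, but whether each listed member is one was not checked. Benzoxazinoid genes fell in 7 of 7 tested cases (Fisher's exact test, adjusted p = 0.000484). Among those that fell were bx2 (-6.28 ± 0.56), the lipoxygenase gene lox10 (-1.86 ± 0.36) and TIFY17 (-2.89 ± 0.45), and Igl, whose product makes free indole, fell by 5.02 ± 0.59. Expansins and cellulose synthases fell in 14 of 18 cases (Fisher's exact test, adjusted p = 2.8e-05), among them expB4 (-5.69 ± 0.57). The fixed defence and stress list had 6 falls and 0 rises of 13, which was not an enrichment (Fisher's exact test, adjusted p = 0.219; 6 over the list alone).

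The table for segment +4 called 7589 of 17969 tested genes, 3497 higher and 4092 lower in q2. The rise of asn3, from 9.61 to 628 FPKM (6.03 ± 0.33), was again the largest among named genes in the authors' deposited table, and sci1, also named maize proteinase inhibitor, rose by 4.55 ± 0.35. The myb-related gene MYBR87 (-4.55 ± 0.84) and the glutathione transferase gene GST25 (-4.69 ± 0.63) fell. With at least 2-fold change 3735 genes were called, 1302 higher and 2433 lower.

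At segment +10, the leaf tip, light-harvesting genes were again lower and heat shock genes higher in q2. Light-harvesting genes fell in 15 of 21 cases and rose in 0 (adjusted p = 4.59e-05, Fisher's exact test). Their median of -0.89 lay below the central 95% of random lists matched on expression, -0.64 to 0.13 (percentile 0.07). It lay at the edge of but within the central 95% of random lists of the closest abundance, -0.90 to -0.14 (percentile 2.88). That closer match has the same limit as at +4. At +10, 56 of the 84 other genes of at least 1000 FPKM were lower. The authors' deposited table lists cab-m1 from 2565 to 46.6 FPKM (fell by 5.78 ± 0.31) and psad1 from 717 to 101 FPKM (-2.82 ± 0.27). C4 core genes fell in 8 of 16 cases and rose in 2 (10 over the list alone), short of the threshold (Fisher's exact test, adjusted p = 0.0641). The C4 core median of -0.48 lay within the central 95% of random lists of the closest abundance, -0.91 to 0.01 (percentile 45). Of C4 core genes of at least 1000 FPKM, 2 of 7 were lower, against 63 of 87 other genes of that abundance. The added list of C4 genes chosen by symbol, which shares members with the C4 core, had 8 falls and 2 rises of 13 at +10 (Fisher's exact test, adjusted p = 0.0221). Its median of -0.48 lay within the central 95% of matched random lists, -0.60 to 0.29 (percentile 6.67). Mesophyll markers fell in 6 of 8 cases with 0 rises (Fisher's exact test, adjusted p = 0.0165; 6 over the list alone), and bundle sheath markers fell in 1 of 8 and rose in 1 (2 over the list alone). The mesophyll median of -0.53 lay within the central 95% of random lists matched on expression, -0.81 to 0.28 (percentile 15.2). Genes above 1000 FPKM, light-harvesting genes among them, had a median of -0.79 at +10 (65 of 94 lower). For the mesophyll markers, the C4 core and the C4 genes chosen by symbol, a fall beyond that of equally abundant genes was not shown. For light-harvesting genes it was not settled. In the authors' deposited table pep1 fell from 10125 to 5336 FPKM (-0.92 ± 0.47), and falls were also called for the Golden2-like factor gene glk1 (-1.30 ± 0.25) and for pDCT1 (-1.24 ± 0.26). The gene alt GRMZM2G088064 rose by 2.70 ± 0.49 and GRMZM2G094712 by 1.67 ± 0.27.

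Benzoxazinoid genes fell in 7 of 7 tested cases at segment +10 (Fisher's exact test, adjusted p = 0.000444), with bx1 from 890.4 to 10.0 FPKM (-6.47 ± 0.32), and genes of the jasmonate list fell in 12 of 15 (adjusted p = 6.5e-05). TIFY genes fell in 11 of 16 cases (Fisher's exact test, adjusted p = 0.00124), among them TIFY28 (-3.22 ± 0.60). Expansins and cellulose synthases fell in 9 of 13 cases (Fisher's exact test, adjusted p = 0.00399), with CesA-4 lower (-4.02 ± 0.32), and aquaporins in 10 of 17 (adjusted p = 0.0107). Heat shock proteins rose in 10 of 15 cases and fell in 0 (Fisher's exact test, adjusted p = 0.00224; 10 over the list alone), with hsp18 from 179.7 to 1105 FPKM (2.62 ± 0.30) in the authors' deposited table. Ribosomal protein genes rose in 13 of 35 cases (7 at an adjusted p under 0.01) and fell in 1, fewer falls than among other genes (Fisher's exact test, adjusted p = 0.0268). The fixed defence list had 1 rise and 4 falls of 10 (Fisher's exact test, adjusted p = 0.508 for falls; 5 over the list alone).

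The table for segment +10 called 7128 of 16272 tested genes, 3506 higher and 3622 lower in q2. asn3 rose from 10.1 to 1058 FPKM (6.71 ± 0.32), the glyoxylate cycle gene mas1, malate synthase, by 5.68 ± 1.36 (3.62 with a pseudocount of 1 FPKM) and the vacuolar aquaporin gene tip3a by 5.08 ± 1.05 in the authors' deposited table. MYBR87 (-7.27 ± 0.86), znod1 (-6.12 ± 1.38) and the cytochrome P450 gene CYP92C5 (-5.91 ± 0.45) fell. With at least 2-fold change 2814 genes were called, 1122 higher and 1692 lower.

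**Figure D1:**
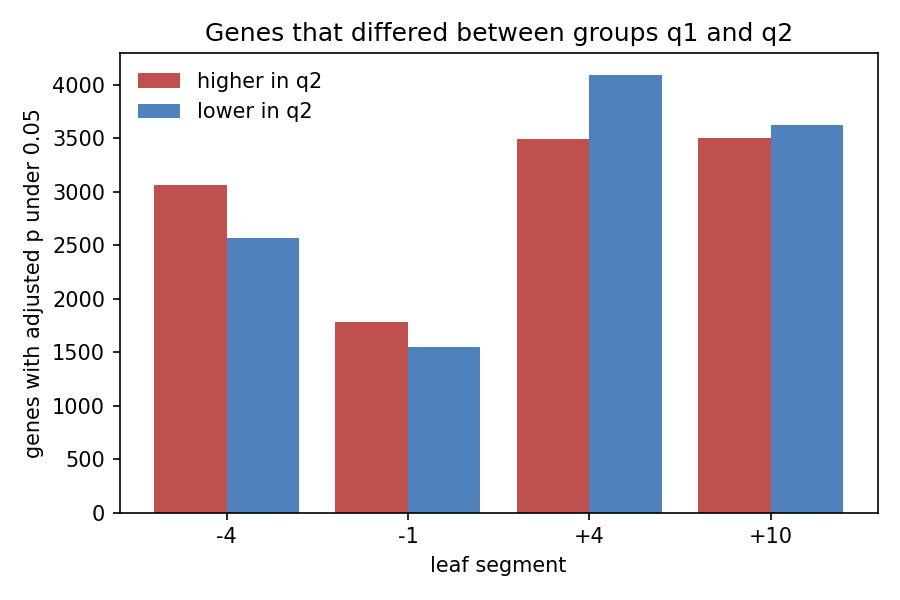
Number of genes with an adjusted p under 0.05 in the authors' deposited table of each leaf segment, split into those higher and lower in q2. There were 1784 higher and 1546 lower at segment -1 and 3497 higher and 4092 lower at +4; with a 2-fold minimum the fewest were at -4 (1406).

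Of 41 pairs of a list and a segment that passed Fisher's exact test, 35 had a median outside the central 95% of random lists matched on expression and 6 had one inside. The 41 include ribosomal proteins at +10, which passed only for having few falls. Some lists share members, so the 41 are not separate findings. With random lists drawn from the 50 closest non-members, 33 lay outside and 8 inside, the added ones being light-harvesting genes at +4 and +10. The heat shock, jasmonate and benzoxazinoid lists passed in all 4 segments, and others did not. Light-harvesting genes had 0 rises and 2 falls of 21 at -1. The Rubisco and Calvin-Benson list chosen by symbol had 1 rise and 1 fall of 11 at -1, 1 and 5 at +4 and 3 and 2 at +10. Genes of DNA replication, cell cycle and histones had 1 rise and 1 fall of 26 at -1, 3 and 13 of 30 at +4 and 4 and 9 of 21 at +10 (Fisher's exact test, adjusted p = 0.0792 for falls at +4). The median of that list still lay below the central 95% of random lists matched on expression at +4 (-0.60, percentile 0.05) and +10 (-0.39, percentile 0.68). It lay inside them at -1 (percentile 20.65). Ribosomal protein genes had 0 rises and 1 fall of 39 at -1 and 3 and 3 of 37 at +4. Expansins and cellulose synthases had 1 rise and 5 falls of 18 at -1 (Fisher's exact test, adjusted p = 0.0763). Aquaporins had 3 rises and 2 falls of 17 at -1 and 3 and 7 of 19 at +4. Anthocyanin and flavonoid genes had 1 rise and 1 fall of 8 at -4, 1 and 6 of 11 at +4 and 1 and 3 of 10 at +10. Lignin genes had 4 rises and 0 falls of 9 at -4. Some of these lists, though short of Fisher's threshold, had medians outside random lists matched on expression. Among them were aquaporins at -1 (0.23, percentile 98.9) and +4 (-0.78, percentile 0.42), anthocyanin and flavonoid genes at +4 (-0.91, percentile 0.53) and lignin genes at -4 (0.47, percentile 98.3). C4 genes chosen by symbol had 3 rises and 4 falls of 15 at -1 and 3 and 5 of 12 at +4, and the fixed Calvin-Benson list had 1 rise and 0 falls of 4 at +10 (1 over the list alone).

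The next question was which genes changed in the same direction along the whole leaf. Of 14633 genes tested in all 4 tables, 320 were higher and 177 lower in q2 in each, against 9.47 and 4.41 expected from independent lists. In every segment a larger share was called at 100 to 1000 FPKM than at 1 to 5 FPKM (58.8% and 35.6% at +4). Expected counts here and below ignore this and may be too low. The higher set held asn3, hsp18, hsp82, hsp18c, hsp18f, bZip112, GLK44 and lkrsdh1, a lysine breakdown gene, and the lower set held pDCT2, the ent-kaurene synthase gene eks1, cpi2, TIFY25, AGP2 and the benzoxazinoid genes bx1, bx2, BX3, BX5 and bx8. In the authors' deposited tables eks1 changed by -2.17 ± 0.35, -1.89 ± 0.34, -2.42 ± 0.30 and -2.70 ± 0.26 from segment -4 to +10, and hsp18c rose by 2.43 ± 0.27, 2.33 ± 0.42, 2.83 ± 0.54 and 1.69 ± 0.38. Segments +4 and +10 shared 2267 higher and 2438 lower genes of 16034 tested in both (721 and 758 expected; Fisher's exact odds ratios 20.3 and 25.7). Segments -4 and +4 shared 755 and 565 (531 and 391 expected), while 761 genes were higher at -4 and lower at +4 (598 expected) and 270 were lower at -4 and higher at +4 (347 expected). Across genes of at least 1 FPKM, which are not independent replicates, the log2 changes correlated at Pearson r = 0.81 between +4 and +10 and at 0.15 between -4 and +4.

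**Figure D2:**
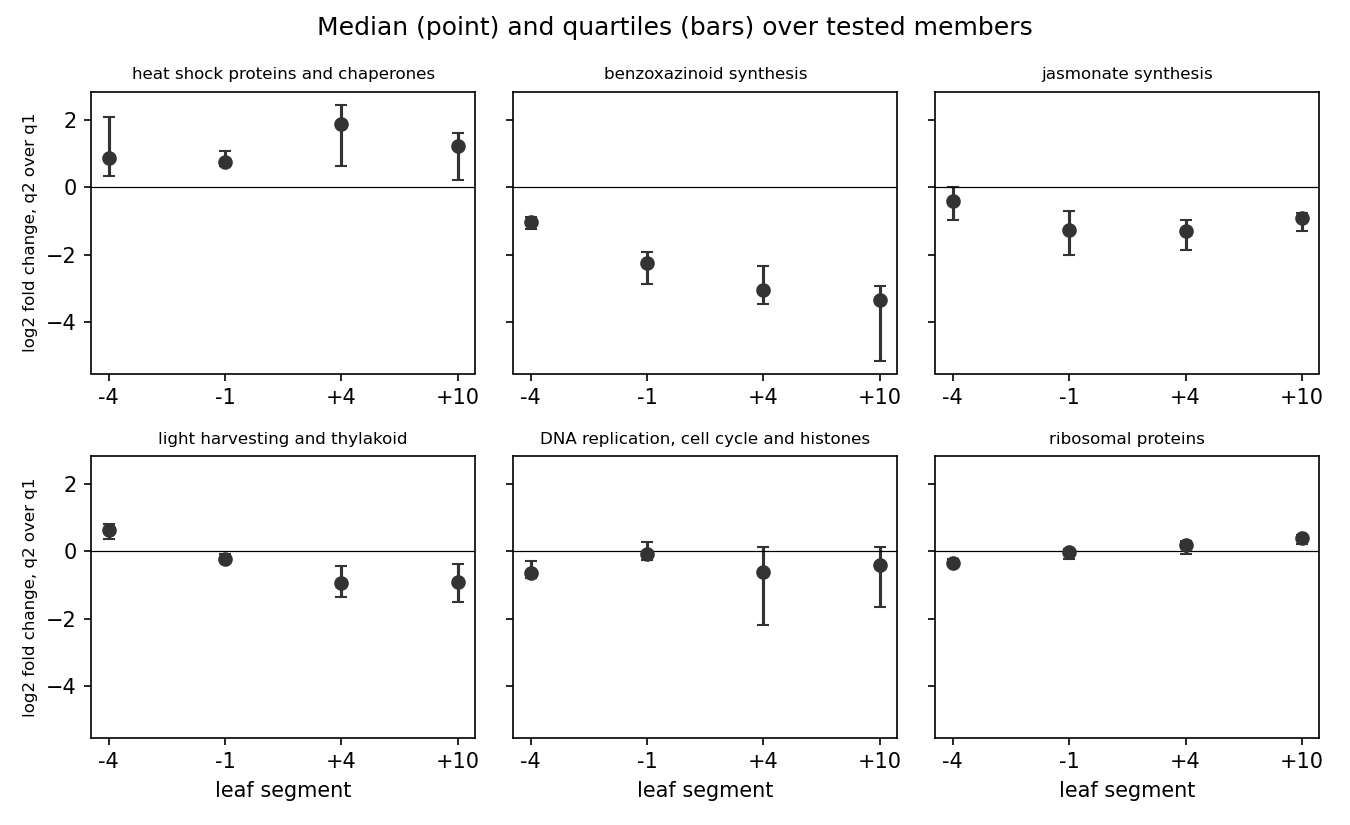
Median log2 fold change, q2 over q1, of 6 gene groups in each leaf segment, with bars from the lower to the upper quartile of the tested members. The median for light-harvesting genes was 0.64 at segment -4 and -0.94 at +4, and that for benzoxazinoid genes went from -1.03 at -4 to -3.35 at +10.

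The last comparison asked whether the difference between q2 and q1 itself depended on the segment. pDCT2 fell less at segment -4 than at +4, with a difference of 3.88 ± 0.43 in log2 change. As listed, its q2 level was about equally low in both segments, so the smaller fall at -4 goes with a lower q1 level there. The differences given here passed a normal test on the implied standard errors, adjusted over all genes. The change at -4 minus that at +4 was 4.18 ± 0.52 for lhcb3, 6.37 ± 0.63 for expB4 and 6.03 ± 0.50 for znod1. For hsp82 the changes at -4, -1 and +10 minus that at +4 were -2.21 ± 0.46, -2.56 ± 0.50 and -2.41 ± 0.45. In all, 1555 of 16374 genes differed between -4 and +4, 593 of 16995 between -1 and +4, and 76 of 15993 between +10 and +4. In simulated data the test recovered 51% of 4-fold and 2% of 2-fold differences between -4 and +4, so many smaller differences may be missed. The simulation planted 200 differences, fewer than the 1555 called, so the shares recovered in the data may differ.

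**Figure D3:**
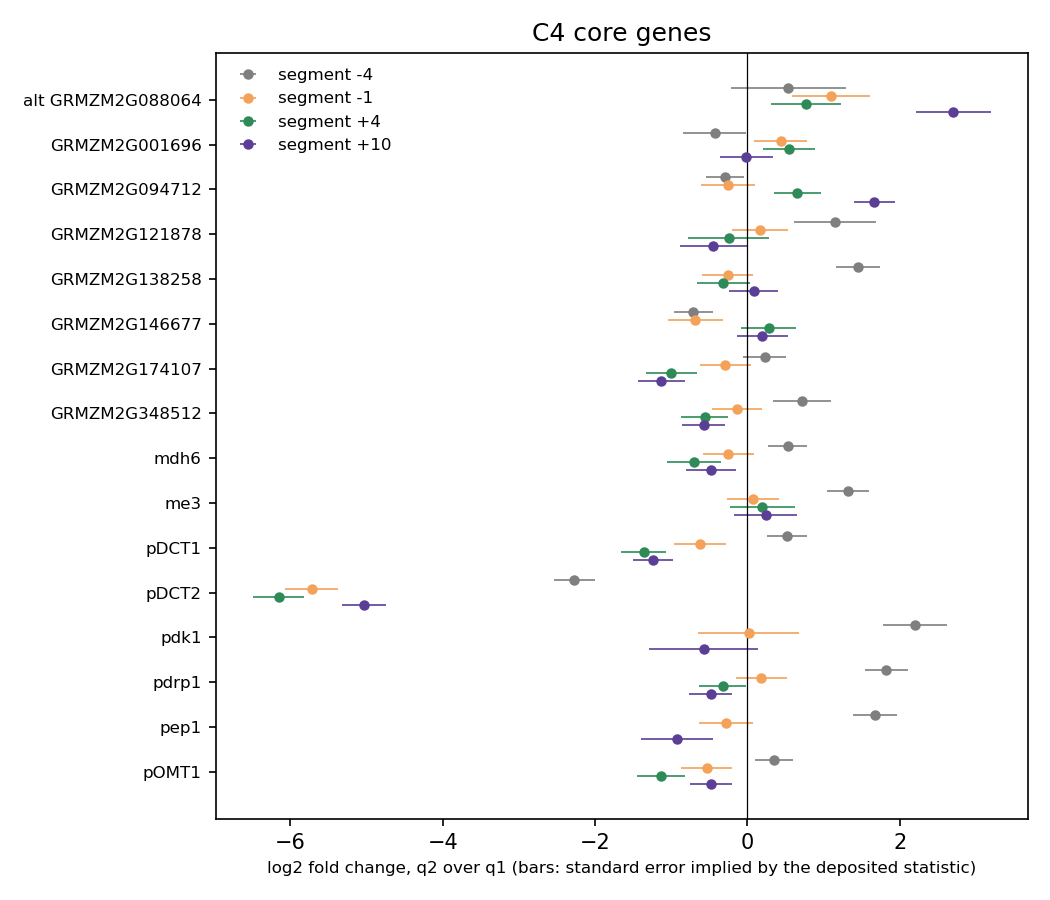
Log2 fold change, q2 over q1, of the 16 C4 core genes in each leaf segment, with bars of 1 standard error implied by the deposited statistic; points without a test in the deposited table are not drawn. pDCT2 lay at -2.27 at segment -4 and between -6.15 and -5.03 in the other segments, and pdk1, pdrp1, pep1 and me3 lay above 0 at -4.

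Levels along the leaf can be set side by side only as listed, since each table may have been scaled on its own. In the authors' deposited tables pDCT2 in q1 stood at 37.8, 657, 633 and 310.4 FPKM from segment -4 to +10. me3 in q1 stood at 31.4, 2737, 3258 and 2935 FPKM, and in q2 at 78.5, 2874, 3729 and 3468 FPKM. No test was run across tables on levels.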

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

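Tests of scaling for the 3 patterns weighed here were chosen after the patterns had been seen; the tests of a chromosome block, of a batch and of the leaf gradient were written down before their results were seen, but how the outcome for the block was read was settled after its values were seen. No count over other splits of the samples was possible, because values for single libraries were not analysed here. All directions are q2 relative to q1.

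The difference between q2 and q1 was tested between segments, and 3 counts of genes stand out. The log2 change at segment -4 differed from that at +4 for 1555 genes, that at -1 for 593 genes and that at +10 for 76 genes. Among C4 core genes, the change at -4 minus the change at +4 was 3.88 for pDCT2, 2.15 for pdrp1, 1.88 for pDCT1, 1.77 for GRMZM2G138258, 1.48 for pOMT1 and 1.23 for mdh6, each past the adjusted threshold of 0.05 in the normal test on the implied standard errors. For pDCT2 the listed q2 level was about equally low at -4 and +4, and the q1 level was lower at -4.

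At segment -4, photosynthesis genes were higher and cell cycle genes lower in q2. A scaling difference would move both groups alike, but their medians lay 1.29 apart (log2) on opposite sides of the median gene. The pattern was picked after its directions had been seen, so this outcome was known beforehand. A candidate explanation is that q2 tissue at -4 was further along the gradient from base to tip: across 17094 genes, which are not independent replicates, the change at -4 correlated with the -4 to -1 gradient of q2 itself at r = 0.35, although the q2 level shared by both measures pulls that value below 0. With the q1 gradient from -1 to +4, which shares no value with the change at -4, r was much weaker, at 0.08 over 15894 genes. Low cell cycle medians were not limited to -4, since those at +4 and +10 (-0.60 and -0.39) also lay below random lists matched on expression. The levels behind the gradient come from separately made tables, and whether sampling position, growth rate or genotype would underlie such a shift stays open.

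Benzoxazinoid genes were lower in q2 in every segment. The list median relative to the median gene was -1.06 at its nearest. A uniform scaling difference would move the median gene as well, but the pattern was picked for standing apart from other genes, so this outcome was known beforehand. Of the 8 genes, 6 lie together on chromosome 4 (BX3 at 2998633 to bx2 ending at 3262840), so a block of that chromosome that differs between the lines stays possible. The count of genes on other chromosomes called lower in all 4 segments, each by over 2 implied standard errors, was 0: bx9 on chromosome 1, which lies within 10 Mb of pDCT2 (180306605 to 180308510), was called lower in all 4 but at -1 with a log2 change of only -0.53 ± 0.33, and BX14 on chromosome 2 fell at -4 (-1.94 ± 0.38) and -1 (-1.73 ± 0.62) and was not tested at +4 and +10. An effect of the genotype on the pathway is untested and open as well.

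Heat shock genes were higher in q2 in every segment. Their median stayed at least 0.76 above the median gene. A uniform scaling difference would move the median gene as well, but the pattern was picked for standing apart from other genes, so this outcome was known beforehand. A difference in growth or harvest batch between the 2 groups cannot be told apart from genotype, because the tables used here hold 0 values for single libraries and the labels give no batch. The genotype remains an open, untested explanation.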

How the results depend on the processing

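No paired analysis was possible because the tables used here carry 1 value per group and no replicate numbers. For the same reason leaving out each replicate, a replicate block and a pseudocount of 0.1 on values per library were planned and not run, and read depth, being unknown, limits precision in ways that cannot be stated. All alternatives here were planned before the data were examined. The fall of pDCT2 kept its direction in all 4 segments with a pseudocount of 1 FPKM (from -6.00 at +4 to -2.14 at -4) and after centring on the median gene (from -6.17 to -2.29). Centring turned the direction of none of the calls, but it shifted values by only 0.0072 to 0.0213 in log2 and could hardly have done so. The 1 FPKM filter and adjustment over all 4 segments together moved no count by over 1.5 times. The joint adjustment gave 5819, 3933, 7246 and 6769 calls from -4 to +10. Adjustment over tests with status OK left every count unchanged, as it repeats the deposited adjustment, and is no separate check. Among list medians and named genes, 79 values (5 lists, 74 genes) moved by more than their spread with a pseudocount of 1 FPKM, all to a smaller size, such as the expansin median at +10 from -2.73 to -1.54, and 746 did not. At an adjusted p under 0.01, 42 counts of calls in lists moved by over 1.5 times and 224 did not. The only change of sign under pseudocount or centring was the median of the cytokinin list at +4, from 0.01 to -0.01 when centred.

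An adjusted p under 0.01 left 3708 calls at -4 (1613 lower) and 2035 at -1 (1106 higher, 929 lower), and 919, 329 and 43 genes whose change differed from +4 at -4, -1 and +10. At least 2-fold change left 1406 calls at -4 (1051 higher, 355 lower), 1589 at -1 (863 and 726), 3735 at +4 (1302 and 2433) and 2814 at +10 (1122 and 1692). For genes changed the same way in a pair of segments, p under 0.01 left 474 higher and 179 lower for -4 and -1, 493 and 315 for -4 and +4, 233 lower for -4 and +10, 391 and 545 for -1 and +4, and 367 and 400 for -1 and +10. The 2-fold minimum left 243 and 81 for -4 and -1, 213 and 85 for -4 and +4, 199 and 61 for -4 and +10, 239 and 357 for -1 and +4, 206 and 237 for -1 and +10, and 646 and 1117 for +4 and +10. These drops follow from the stricter rule itself, which can only remove calls.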

Other observations

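The tests of the plastid and mitochondrial genome lists were added after the first results were seen. The linkage test was written down before its result was seen, but the condition on its interval was added after its value was seen.

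Among genes of nitrogen uptake and assimilation, 6 of 15 rose and 4 fell at segment -4, 2 rose and 7 fell of 16 at +4, and 5 rose and 4 fell of 15 at +10, with no enrichment (Fisher's exact test, adjusted p = 0.0903 for rises at -4). Beside asn3, in the authors' deposited tables the glutamate dehydrogenase gene gdh1 fell at +4 (-1.11 ± 0.33) and +10 (-2.14 ± 0.31), and the glutamine synthetase gene gln5 fell at +10 (-1.55 ± 0.26). Starch genes fell in 6 of 15 cases at -4 (Fisher's exact test, adjusted p = 0.0491; list median -0.02, at percentile 40.1 of random lists matched on expression) and in 7 of 12 at +4 (adjusted p = 0.0525), with 1 rise each, but had 2 falls and 1 rise of 14 at -1 and 4 falls and 2 rises of 10 at +10 (adjusted p = 0.672 and 0.557 for falls); AGP2 and GBSSIIa, a granule-bound starch synthase gene, fell at +4 (-1.46 ± 0.29 and -1.46 ± 0.30). Genes of sucrose metabolism and sugar transport fell in 10 of 20 cases at +4 (Fisher's exact test, adjusted p = 0.0467), among them the sucrose transporter gene sut4 (-2.66 ± 0.87), and the invertase gene ivr2 (-1.88 ± 0.31), which at -4 rose by 1.57 ± 0.28. The list median at +4, -0.32, lay within the central 95% of matched random lists, -0.40 to 0.35 (percentile 5.60). That list had 5 rises and 3 falls of 19 at -4, 2 and 3 of 20 at -1 and 2 and 5 of 21 at +10, with no enrichment (Fisher's exact test, adjusted p = 0.511 for rises at -4, 0.544 for falls at -1 and 0.926 for falls at +10).

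Genes of autophagy and senescence had 5 rises and 3 falls of 19 at -4, 0 and 3 of 20 at -1, 3 and 8 of 19 at +4 and 3 and 9 of 19 at +10. No segment showed an enrichment (Fisher's exact test, adjusted p = 0.222 and 0.107 for falls at +4 and +10). Among its members, see2b went from 148 to 26.3 FPKM at +10 (fell by 2.49 ± 0.26) and ccp2 from 162 to 44.7 FPKM (-1.86 ± 0.26) in the authors' deposited table. Genes of folding in the endoplasmic reticulum had 5 rises and 3 falls of 19 at -4, 0 and 2 of 18 at -1, 4 and 4 of 16 at +4 and 7 and 3 of 14 at +10, with no enrichment (Fisher's exact test, adjusted p = 0.0903 for rises at +10). Their median lay outside random lists matched on expression at -1 (-0.29, percentile 0.85) and at +10 (0.48, percentile 99.1). Among the genes of that list, the chaperone gene bip1 rose by 1.00 ± 0.31, 1.32 ± 0.31 and 1.71 ± 0.28 at -4, +4 and +10, and had a log2 change of 0.27 ± 0.36 at -1. Genes of the plastid genome had 4 rises and 0 falls of 11 at -4 (Fisher's exact test, adjusted p = 0.275), 0 and 1 of 11 at -1, 0 and 0 of 10 at +4 and 3 and 0 of 11 at +10. The list median lay outside random lists matched on expression at -4 (1.25, percentile 99.99) and at -1 (-0.77, percentile 0.01). It lay inside them at +4 and +10 (percentiles 61.1 and 96.1). Those of the mitochondrial genome had 0 rises and 1 fall of 9 at -4 and 0 and 0 of 4 at -1. They had 1 rise and 0 falls of 3 at +4 and 3 and 0 of 6 at +10 (Fisher's exact test, adjusted p = 0.391 for rises at +10). The mitochondrial median lay outside random lists matched on expression at +4 (1.07, percentile 98.2) and +10 (1.30, percentile 99.9). It lay inside them at -4 and -1 (percentiles 84.4 and 55.2). Both lists rest on few members, since they hold 124 mitochondrial and 57 plastid genes.

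A hypothesis was that genes changed the same way in all 4 segments sit near pDCT2 on chromosome 1, as a block carried along with the mutation might give. Within 10 Mb of pDCT2, 4 of 136 tested genes (2.94%) were changed that way, against 492 of 14496 elsewhere (3.39%). The odds ratio was 0.86 (95% interval 0.23 to 2.28; Fisher's exact test, p = 1), which leaves room for an enrichment of up to 2.28 times in the odds, and the tables do not decide it.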
